A study of Mus musculus with 2 samples.

How the data were processed

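B cell receptor (BCR) transcripts were sequenced from single cells of mouse Peyer's patches, the lymphoid follicles of the small intestine in which B cells switch to IgA. Per the labels, cells were enriched for CD45, a surface protein of white blood cells, with magnetic beads, pooled over 4 adult female mice per genotype and loaded on a 10x Genomics Chromium controller. Libraries were made with that maker's 5' V(D)J kit, which amplifies antigen receptor transcripts from droplets that each carry a cell barcode. There were 2 libraries, 1 per genotype. The Cre+ library came from H2-Ab1 fl/fl mice carrying Villin:Cre, in which the gene for the MHC class II beta chain is deleted in intestinal epithelial cells. The Cre- library came from H2-Ab1 fl/fl mice without the recombinase. The genotypes were taken from the label of each sample. The design text of the series writes the Cre-negative genotype for both groups, which the sample labels contradict, and H2-Ab1 itself was not measured, so the files hold no check of the genotype.

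The submitters' processing notes name Cell Ranger and the GRCm38 genome build; the version of Cell Ranger is not given in the sources used here. For each library 2 kinds of table were used. The contig table lists, per the file headers, each assembled receptor transcript with its barcode, chain, V, D, J and constant gene, CDR3 sequence, and the count of reads and of unique molecular identifiers (UMIs), as deposited by the authors. The clonotype table gives the count of barcodes per clonotype, also deposited by the authors, and these counts matched those recomputed from the contig tables in both libraries. The counts were not normalised. All deposited contigs carried the flags for a called cell and for high confidence, so barcodes outside called cells were not analysed here. Gene expression of the same cells was not used here, and cell types were therefore not assigned.

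A heavy chain was a productive IGH contig, with contigs of 1 barcode and identical CDR3 nucleotides collapsed, which happened in 0 barcodes. Main values rest on barcodes with exactly 1 heavy chain, called cells below. Barcodes with 2 or more heavy chains, which can hold 2 cells or stray RNA, were left out; no separate doublet caller was run. Each cell had at most a single constant gene called, so a naive cell that transcribes both IgM and IgD was counted under whichever was assembled. The light chain of a cell was the productive IGK or IGL chain with the most UMIs. Isotype shares were taken over cells with a constant gene called, which left out 18 cells of the Cre+ library and 10 of the Cre- library.

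A lineage was a set of cells of the same library with the same IGHV gene, IGHJ gene and CDR3 length, joined by single linkage at 85% or more CDR3 nucleotide identity. Expansion was compared at the same number of cells in both libraries, as the expected value when that number is drawn without replacement; evenness and the share of the 10 largest lineages were averaged over 1000 random draws. As a background for chance joining, each cell was set against the other library's cells by the same rule of identity, and each unswitched cell against the other library's unswitched cells. Mutation could be read only inside the CDR3, since the tables hold no V region sequence. The proxy was the share of cells with a mismatch in the 9 nucleotides before the last codon of the CDR3, against the most common such sequence of that IGHJ gene in unswitched cells of both libraries. Trimming of the J gene at the joint also gives mismatches, so the unswitched cells serve as its background.

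With 1 pooled library per genotype there is no replicate and no test was made. Shares are given with exact 95% Clopper-Pearson intervals, which cover counting error only; cells of 1 lineage are not independent, so the true uncertainty of a share that a large lineage carries is wider. A difference of 2 shares has an interval combined from both exact intervals. Genes to name were chosen by a rule set before the data were examined: all constant, IGHJ and lambda genes and all IGHV families; the 10 IGHV genes with the most cells over both libraries; up to 10 IGHV genes with 20 or more cells, a ratio of shares of 1.5 or more either way and intervals that did not overlap; and 5 IGKV genes by each of these 2 rules. Where a count was 0, the limit given is 3 cells of the total, unless an exact upper bound is named. Coordinates come from a RefSeq gene table of GRCm38.p6, in which 95 of 95 IGHV names were found.

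Alternatives planned before the data were examined were other rules for barcodes, a minimum of 3 UMIs, each lineage and isotype class counted once, lineages at 80% or 90% identity, identical CDR3s, the authors' clonotypes, lineages that also share the light V gene, 6 or 12 nucleotides of J, mean CDR3 length, and unswitched or switched cells alone. Leaving out the largest lineage, or the 2 largest lineages, of each library was added after the data were seen. The steps were tested on simulated data. IGHV genes were drawn cell by cell from pooled shares, and 64 genes had the minimum number of cells of the naming rule. The rule took 48.4% of genes changed 2-fold, 83.8% of those changed 3-fold and 96.6% of those changed 5-fold. It took 0.423% of unchanged genes when no gene was changed. Beside genes changed 5-fold it took 21.3% of unchanged genes, because shares sum to a fixed total. Cells were drawn singly and not as lineages. These rates therefore do not apply to a gene whose share a large lineage carries. Seeded lineages of 3 cells were joined whole in 92% of cases at a mutation rate of 5% per nucleotide and in 23% at 10%. Of 300 chains given a single changed base in the 9 nucleotides, 300 were found. This outcome was fixed by construction, since all of these chains matched the reference before the change. It checks the code only, and trimming at the joint was not simulated. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.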

Results

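The study asked how the B cell receptors of Peyer's patches compare between mice that lack MHC class II on intestinal epithelial cells and controls that keep it. The Cre+ library, from mice lacking H2-Ab1 in the epithelium, held 3748 barcodes, 12300 contigs and 355258 UMIs from 22003594 reads. The Cre- library, from controls, held 3245 barcodes, 10108 contigs and 355985 UMIs from 19982305 reads. A productive heavy chain was found in 3439 and 3030 barcodes, and exactly 1 heavy chain in 3294 and 2947, which are the cells compared here. A light chain was also found in 3262 of the Cre+ and 2889 of the Cre- cells. The median cell had 8 heavy-chain UMIs in the Cre+ library (interquartile range 5 to 13) and 10 in the Cre- library (6 to 16). Each library pooled 4 mice and there was 1 library per genotype, so no difference below has a replicate check, and all intervals are exact 95% intervals that cover counting error only.

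IgA, the antibody class that is secreted into the gut, was carried by 6.32% of Cre+ cells (207 of 3276, interval 5.51 to 7.21) and by 19.0% of Cre- cells (557 of 2937, 17.6 to 20.4). Its share was thus lower in the Cre+ library, with a difference of -12.6 percentage points (interval -14.3 to -10.99). Of the 557 IgA cells of the control library, 416 belonged to a single lineage. Without the largest lineage of each library the IgA share was 4.79% in Cre+ (4.08 to 5.59) and 5.59% in Cre- cells (4.73 to 6.56), and the intervals overlapped.

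Unswitched cells made up most of both libraries. IgM was found in 58.8% of Cre+ cells (57.1 to 60.5) and 52.5% of Cre- cells (50.7 to 54.3), and IgD in 30.1% (28.5 to 31.7) and 24.6% (23.1 to 26.2). Without the largest lineages IgM stood at 59.7% and 61.2% and IgD at 30.6% and 28.7%, with overlapping intervals in both cases. IgG2b, the most frequent IgG in both libraries, was at 3.05% in Cre+ (2.49 to 3.70) and 3.17% in Cre- cells (2.56 to 3.87). IgG1, the class that T cell help through IL-4 favours, was at 1.68% (55 cells, 1.27 to 2.18) and 0.749% (22 cells, 0.470 to 1.13), a ratio of 2.24. A lineage of 29 cells held 27 of the 55 IgG1 cells of the Cre+ library, and without the 2 largest lineages of each library the IgG1 shares were 0.847% and 0.874%. IgG3 was found in 3 Cre+ cells and 0 Cre- cells, which allows a share of up to 0.102% in the latter. IgG2a, IgG2c and IgE were found in 0 cells of either library, which allows up to 0.0916% in Cre+ and 0.102% in Cre- cells. The constant genes lie on chromosome 12 of GRCm38, from Igha at 113256204 to 113260236 up to Ighm at 113418826 to 113422730.

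**Figure D1:**
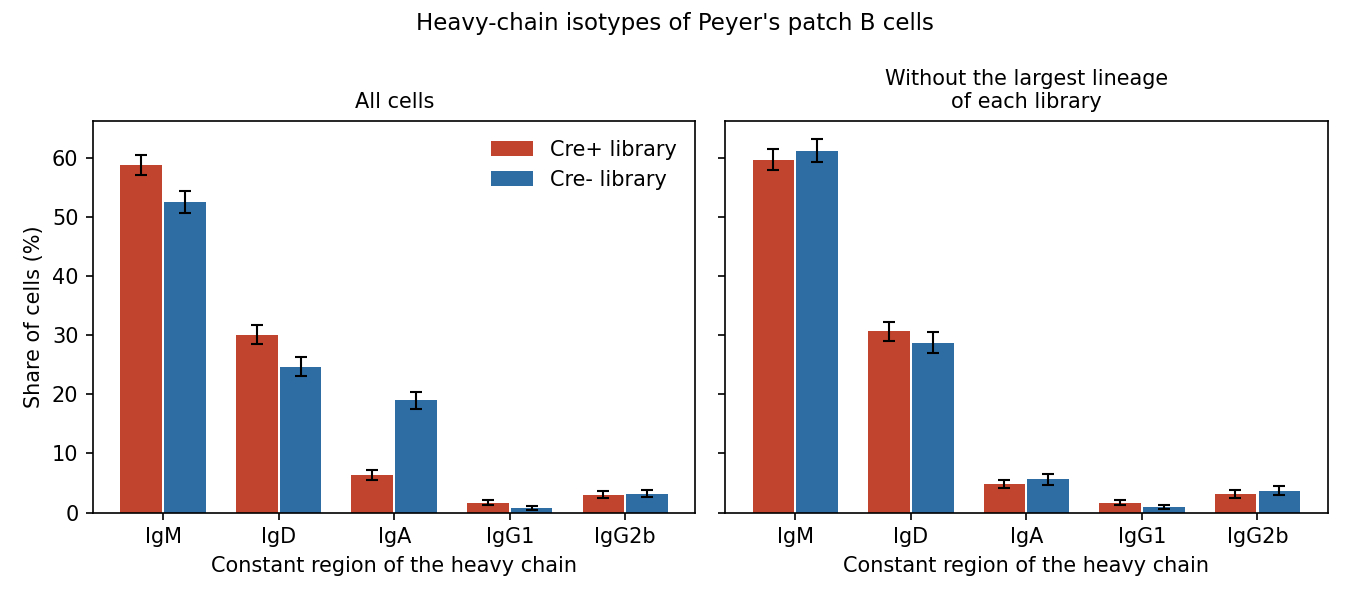
Share of cells (%) by heavy-chain constant region in the Cre+ and Cre- libraries, for all cells (left) and without the largest lineage of each library (right); bars are shares and error bars exact 95% intervals of counting error. The IgA bars stand at 6.32% and 19.0% on the left and at 4.79% and 5.59% on the right.

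The largest lineage of the control library held 417 of its 2947 cells, or 14.2% (12.9 to 15.5). It joined IGHV4-1 to IGHJ3 with the CDR3 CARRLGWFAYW, encoded by the same nucleotides, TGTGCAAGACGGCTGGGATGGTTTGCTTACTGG, in all 417 cells. Its light chain was IGKV9-123 with the CDR3 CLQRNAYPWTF in 385 cells, and 23 cells had no light chain. The constant gene was IGHA in 416 cells and not called in 1. The next set joined by the lineage rule in that library had 5 cells, with 5 different CDR3s (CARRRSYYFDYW among them), each in 1 cell. Cells of this lineage had a median of 19 heavy-chain UMIs (interquartile range 13 to 27, highest 57) but only 5 light-chain UMIs. The median ratio of light to heavy UMIs was 0.263 in this lineage, against 2.49 in the other IgA cells of the library and 3.56 in its unswitched cells.

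The largest lineage of the Cre+ library held 64 cells, or 1.94% (1.499 to 2.47). It joined IGHV5-17 to IGHJ4, with the CDR3 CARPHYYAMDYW in 62 cells. Of its cells, 53 were IgA, 7 IgM, 1 IgD and 1 IgG1, and 2 had no constant gene called. The light chain IGKV4-72 with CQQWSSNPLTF was the main one in 48 of them. Its cells had medians of 8 heavy-chain and 7 light-chain UMIs and a median light to heavy ratio of 0.866, against 2.56 in the other IgA cells of the library, so a low ratio was found in both largest lineages. The same heavy-chain CDR3 stood beside another heavy chain in 15 further barcodes. The second lineage, of 29 cells, was IGHV1-9 and IGHJ2. It carried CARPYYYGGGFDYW in 18 cells and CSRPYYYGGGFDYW in 10, was IgG1 in 27, and had an IGKV1-110 light chain in 28. The next lineages, of 8 and 6 cells, both used IGHV1-12 and IGHJ2, and 7 cells of the former were IgA.

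**Figure D2:**
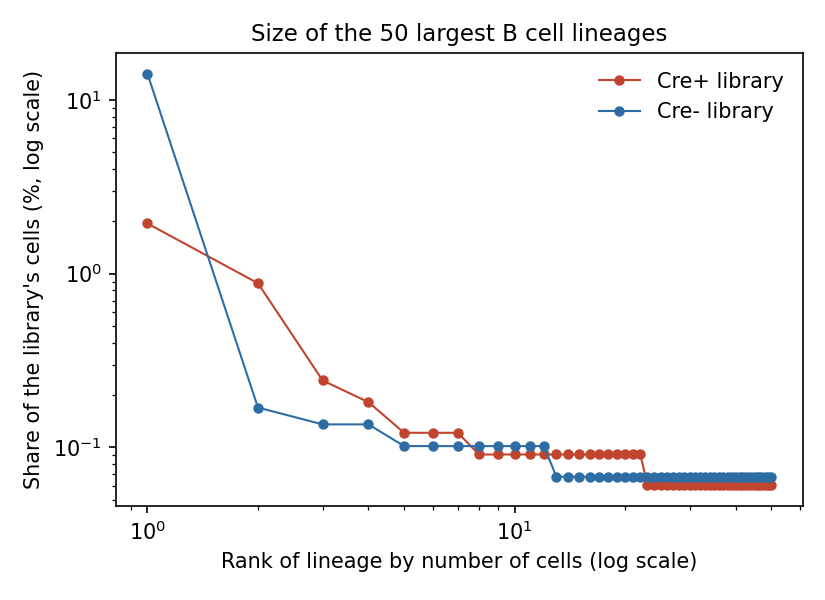
Share of each library's cells (%, log scale) held by each of its 50 largest lineages, against the rank of the lineage (log scale), for the Cre+ and Cre- libraries. The first lineage holds 14.2% of the Cre- and 1.94% of the Cre+ cells, and the second 0.170% and 0.880%.

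**Figure D3:**
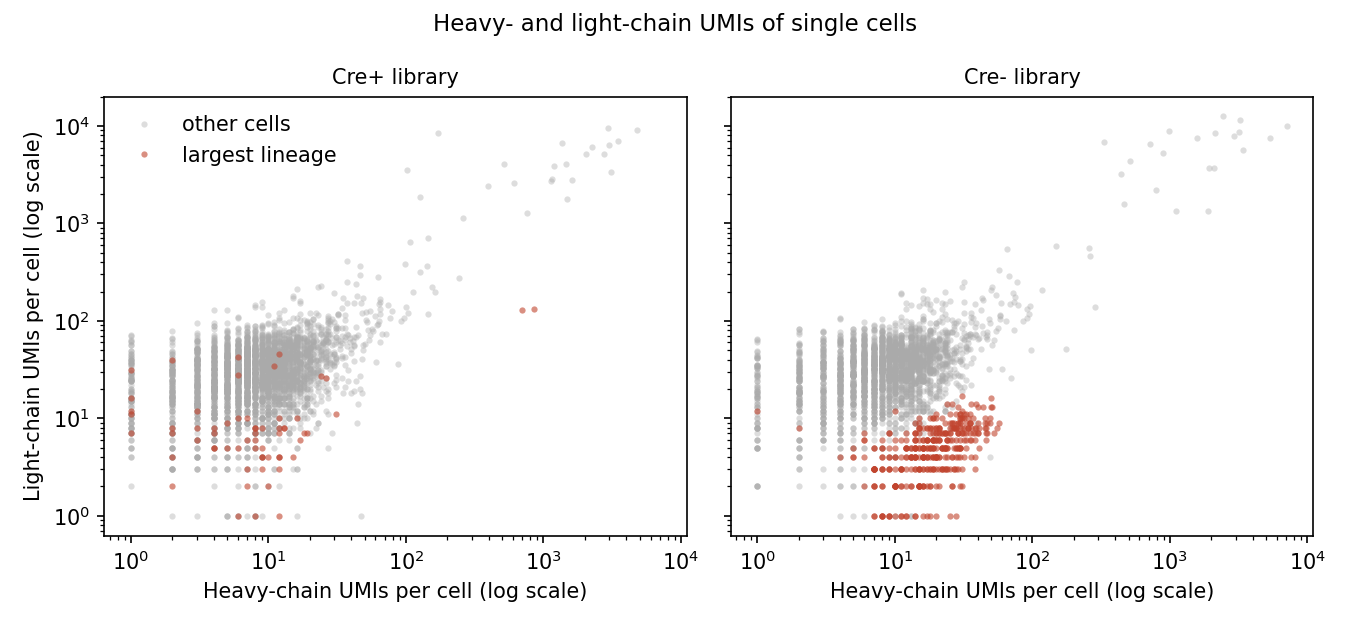
Light-chain against heavy-chain UMIs of each cell with a light chain (both log scale), Cre+ library on the left and Cre- library on the right, with the largest lineage of each in red and other cells in grey. The median light to heavy ratio was 0.263 in the Cre- and 0.866 in the Cre+ lineage, against 3.56 and 3.46 in the unswitched cells of these libraries.

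Cells in lineages of 2 or more were fewer in the Cre+ library. At 2947 cells in both, 9.58% of Cre+ and 19.5% of Cre- cells lay in lineages of 2 or more cells, and the 10 largest lineages held 3.93% and 15.2% of cells. The effective number of lineages, the exponential of the Shannon entropy of lineage sizes, was 2497 in the Cre+ and 1201 in the Cre- library. This order rested on the control library's largest lineage, for which a true expansion and stray RNA cannot be told apart, as given below. Without the largest lineage of each, at 2530 cells, the shares in lineages of 2 or more were 7.15% and 6.28%. Unswitched cells were seldom expanded in either library, with 3.81% and 3.84% in lineages of 2 or more at 2265 cells. As a background for chance joining, 3.30% of the 2911 unswitched Cre+ cells (2.68 to 4.01) had a partner at the same identity among the 2265 unswitched cells of the other library, and 4.28% of the 2265 unswitched Cre- cells (3.49 to 5.20) had one among the 2911. The number of cells searched differs from that within a library. Among IgA cells, 50.7% of Cre+ and 77.6% of Cre- cells were in such lineages at 207 cells, and 32.0% and 23.4% at 141 cells without the largest lineages. Among IgG cells the shares were 30.6% and 17.4% at 115 cells, and without the 2 largest lineages of each library 19.1% and 17.4%.

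Of the IGHV genes, IGHV4-1 differed most, at 0.789% of Cre+ cells (26 cells, 0.516 to 1.15) and 14.8% of Cre- cells (436 cells, 13.5 to 16.1), a log2 ratio of -4.23. IGHV5-17 was at 4.13% (3.48 to 4.87) and 2.17% (1.68 to 2.76), with a log2 ratio of 0.93. IGHV1-9 was at 3.31% (2.72 to 3.98) and 1.90% (1.44 to 2.46), with a log2 ratio of 0.80. IGHV1-12 was at 1.79% (59 cells, 1.37 to 2.30) and 0.679% (20 cells, 0.415 to 1.05), with a log2 ratio of 1.40. These were the genes past the rule of size. The first 3 are the V genes of the largest lineages, and without the largest lineage of each library IGHV4-1 was at 0.805% and 0.751% and IGHV5-17 at 2.23% and 2.53%. Without the 2 largest of each, IGHV1-9 was at 2.50% and 2.22%. IGHV1-12 kept intervals apart in both cases, but not with each lineage and isotype class counted once, at 1.45% and 0.733%. In switched cells outside the largest lineage of each library, IGHV1-12 was used by 22 of 311 Cre+ and 4 of 256 Cre- cells. The Cre+ count includes IGHV1-12 lineages of 8, 6 and 4 cells, most of them switched, so it is not a count of independent cells. In unswitched cells IGHV1-12 was used by 1.24% (0.868 to 1.71) and 0.706% (0.404 to 1.14).

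On chromosome 12 of GRCm38, the V segments lie at 113859149 to 113859442 (Ighv5-17), 113948284 to 113948577 (Ighv4-1), 114583569 to 114583862 (Ighv1-9) and 114615850 to 114616143 (Ighv1-12). Among the genes with the most cells, IGHV1-26 led the Cre+ library, with 6.62% of cells against 5.12% in the Cre- library. The others were IGHV1-64 (3.70% and 3.16%), IGHV3-6 (3.31% and 3.46%), IGHV1-82 (3.10% and 2.92%), IGHV1-72 (3.28% and 2.61%), IGHV9-3 (3.13% and 2.58%) and IGHV1-80 (2.34% and 3.12%). In unswitched cells no IGHV gene passed the rule of size. Across 64 IGHV genes the shares of both libraries correlated with a Pearson r of 0.378 and a Spearman rho of 0.860, and with an r of 0.940 and a rho of 0.913 without the largest lineages; genes are not independent replicates.

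**Figure D4:**
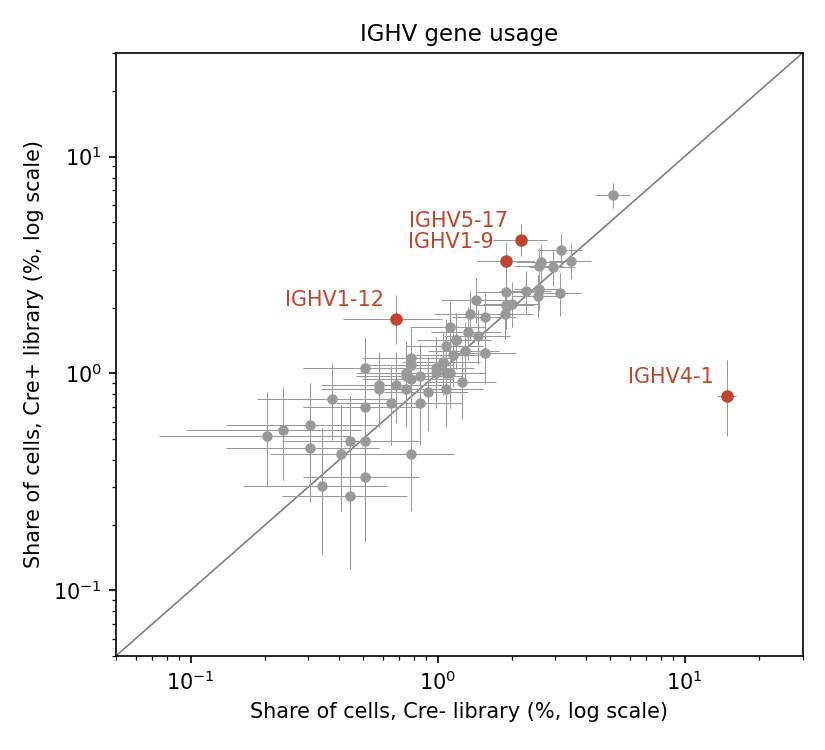
Share of cells (%) using each of 64 IGHV genes in the Cre+ library against the Cre- library (both log scale), with exact 95% intervals as bars and equal shares as the diagonal line. IGHV4-1 lies far from the line, at 14.8% of Cre- and 0.789% of Cre+ cells, and the other genes in red are IGHV5-17, IGHV1-9 and IGHV1-12.

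Differences in the families IGHV1, IGHV4 and IGHV5 rested on the largest lineages, and without these their intervals overlapped. IGHV1, the largest family, was used by 62.0% of Cre+ and 53.5% of Cre- cells, IGHV5 by 9.02% and 6.38%, and IGHV4 by 0.789% and 14.8%. IGHV8, the family of no lineage named above, was used by 4.07% and 2.85%. Without the largest lineages IGHV8 was at 4.15% (3.49 to 4.89) and 3.32% (2.66 to 4.09), with overlapping intervals. IGHV9 was at 4.80% and 3.63%, IGHV3 at 4.34% and 4.28%, IGHV2 at 3.95% and 3.94%, IGHV6 at 3.73% and 3.36%, and IGHV14 at 3.46% and 3.53%. IGHV10, IGHV7, IGHV13, IGHV15, IGHV11 and IGHV12 were each below 2% in both. The families nearest to the D segments, IGHV2 and IGHV5, summed to 13.0% and 10.3%, and the distal families IGHV1 and IGHV8 to 66.0% and 56.4%. Without the largest lineages these sums were 11.2% and 12.02%, and 67.3% and 65.7%.

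IGHJ3, the J gene of the control library's largest lineage, was used by 21.7% of Cre+ cells (20.3 to 23.1) and 32.3% of Cre- cells (30.6 to 34.0). Without the largest lineages it was at 22.1% and 21.1%. IGHJ1 was at 16.9% and 16.2%, IGHJ2 at 36.3% and 30.4%, and IGHJ4 at 25.1% and 21.1% of all cells. These became 17.3% and 18.8% for IGHJ1, 37.0% and 35.5% for IGHJ2 and 23.6% and 24.6% for IGHJ4 without the largest lineages, with overlapping intervals for each. In unswitched cells IGHJ3 was at 22.1% and 20.4%. In switched cells without the largest lineages, the difference was 11.5 percentage points for IGHJ2 (44.7% and 33.2%, 3.18 to 19.6). It was -6.53 for IGHJ1 (12.2% and 18.75%, -12.9 to -0.334). Intervals of the shares overlapped for both genes, and for IGHJ3 and IGHJ4 the interval of the difference included 0. The Cre+ IgG1 lineage of 29 cells, which uses IGHJ2, was still included there. Among the 2953 Cre+ and 2725 Cre- cells with a D gene called, IGHD1-1 led with 36.4% and 29.98%, and IGHD4-1, the D gene called in the control library's largest lineage, was at 12.9% and 24.6%. With the largest lineage of each library left out, IGHD1-1 was at 36.4% and 35.4% and IGHD4-1 at 12.9% and 10.9%. The intervals of these shares overlapped, but that of the IGHD4-1 difference, 1.95 percentage points, ran from 0.156 to 3.72.

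Kappa light chains repeated the pattern of their lineages. IGKV9-123 was found in 4 of 3113 Cre+ kappa cells (0.128%, 0.0350 to 0.329) and 389 of 2766 Cre- kappa cells (14.1%, 12.8 to 15.4). IGKV4-72 was at 2.86% (2.30 to 3.51) and 1.19% (0.823 to 1.67). Neither passed the rule of size without the largest lineages. The other IGKV genes with the most cells were IGKV10-96 (5.59% and 4.52%), IGKV1-117 (5.08% and 3.58%), IGKV1-110 (4.56% and 3.83%) and IGKV1-135 (3.63% and 3.43%). On chromosome 6, Igkv9-123 lies at 67954230 to 67954690 and Igkv4-72 at 69226854 to 69227383. Lambda chains were carried by 4.57% of Cre+ cells (3.88 to 5.34) and 4.26% of Cre- cells (3.55 to 5.06), with overlapping intervals. Among lambda cells, IGLV1 made up 74.5% and 62.6%, IGLV2 14.8% and 21.1%, and IGLV3 10.7% and 16.3%. The difference was 11.9 percentage points for IGLV1 (0.330 to 23.3), -6.37 for IGLV2 (-16.2 to 3.22) and -5.52 for IGLV3 (-14.5 to 3.07). Lambda was found in 1.13% of switched Cre+ cells (0.309 to 2.87) against 4.98% of unswitched ones (4.22 to 5.84), and in 1.41% of switched Cre- cells (0.645 to 2.65) against 5.09% (4.22 to 6.08). Without the largest lineages, whose main light chains are kappa, the switched shares were 1.33% (0.363 to 3.37) and 3.64% (1.68 to 6.80), and the latter overlapped that of unswitched Cre- cells.

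The heavy-chain CDR3 had a median of 14 amino acids in both libraries (interquartile range 12 to 16 in Cre+ and 11 to 16 in Cre- cells). In IgA cells the median was 12 in the Cre+ and 11 in the Cre- library, the length in the control library's largest lineage, and 13 and 14 without the largest lineages. A mismatch to the J gene within the CDR3, a mark that mutated chains carry more often, was found in 15.4% of unswitched Cre+ cells (14.1 to 16.7) and 15.3% of unswitched Cre- cells (13.8 to 16.8). In IgA cells it was found in 34.3% (27.9 to 41.2) and 9.34% (7.05 to 12.1). Without the largest lineages, which both lack a mismatch, it was found in 46.1% of the IgA cells of the Cre+ library (38.1 to 54.3) and 36.9% of those of the Cre- library (28.9 to 45.4), with overlapping intervals. In both, IgA cells were then above the unswitched cells, with all J genes pooled. The background depended on the J gene, and neither IgA nor IgG shares were adjusted for IGHJ usage. Without the largest lineages, unswitched cells stood at 29.1% and 29.5% for IGHJ2 and at 3.61% and 3.37% for IGHJ4. Switched cells stood at 33.1% and 38.8% for IGHJ2, overlapping the unswitched intervals, and at 38.8% and 43.6% for IGHJ4. They were also higher for IGHJ1 and IGHJ3. In IgG cells the shares were 26.6% (19.9 to 34.2) and 41.7% (32.6 to 51.3), and without the 2 largest lineages of each library, which include the IgG1 lineage of 29 cells, 32.3% (24.4 to 41.1) and 41.7%. The difference was -15.2 percentage points (-26.8 to -3.28) in all IgG cells and -9.43 (-21.9 to 3.22) without those lineages.

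Among lineages of 2 or more cells, 15 of 107 in the Cre+ library (14.0%, 8.06 to 22.1) and 8 of 73 in the Cre- library (10.96%, 4.85 to 20.5) held both unswitched and switched cells. Both IgA and IgG cells were found in 7 and 2 of these lineages. Over 1 CDR3 nucleotide sequence was found in 93 of the 107 and 56 of the 73. Cells joined by chance also differ in CDR3 and may differ in isotype. In the other library, 3.34% of all Cre+ and 3.63% of all Cre- cells (107 of 2947) had a partner at this identity. Once the largest lineages were left out, 8.36% and 6.28% of cells lay in lineages of 2 or more. The former shares count the cells of the largest lineages too, so beside 6.28% the background of the Cre- library is understated. Part of these lineages may thus be chance joins. Where members also had to share the light V gene, 9 of 45 and 1 of 33 lineages held both unswitched and switched cells, and 0.334% and 0.305% of cells had a partner in the other library.

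The libraries shared 0 heavy chains with the same IGHV gene, IGHJ gene and CDR3 amino acids, out of 3171 distinct ones in the Cre+ and 2504 in the Cre- library. Kappa chains, with far fewer possible joints, shared 387 combinations of V gene and CDR3 nucleotides out of 839 and 726. In the 10 barcodes that occurred in both libraries, the same heavy-chain CDR3 was found 0 times. Heavy chains typical of B-1 cells, which recognise phosphatidylcholine (IGHV11-1, IGHV11-2 and IGHV12-3), were found in 3 Cre+ and 1 Cre- cells. The T15 heavy chain of antibodies to phosphorylcholine was found in 0 cells of either library, which allows shares of up to 0.0911% and 0.102%. IGHV1-72 with a lambda chain, the pair typical of responses to the hapten NP, was found in 3 and 2 cells. No difference in these rare receptors was detectable at this depth.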

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

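All tests below were chosen after the results were seen, except that of distances between barcodes. Some signals outside the cells compared were above the level in the control library, with intervals that did not overlap. Contigs of T cell receptor genes, all of them non-productive, made up 1.29% of Cre+ contigs against 0.861% of Cre- contigs. Contigs joining genes of different loci made up 10.2% against 8.86%. Barcodes with 2 or more heavy chains made up 4.22% of Cre+ barcodes with a heavy chain (3.57 to 4.94) against 2.74% in the control library (2.19 to 3.38); without barcodes that hold a chain of the largest lineage of each library the shares were 3.87% (3.24 to 4.58) and 3.07% (2.44 to 3.80), with overlapping intervals.

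The higher IgA share of the control library rested on its 417-cell lineage. Without the largest lineage of each library the difference was -0.801 percentage points, with an interval of -2.00 to 0.374, against -12.6 with all cells. Presence of MHC class II on the epithelium remains an untested biological explanation, as does a chance expansion in a single mouse, because with 1 library per genotype the genotype, the pool of mice and the library cannot be told apart.

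For the 417-cell lineage itself, RNA spread evenly over all droplets is argued against, since only 0.115% of barcodes with another heavy chain also held this chain (0.0237 to 0.335). Errors in a few barcode sequences are argued against too: the median distance to the nearest barcode of the lineage was 6 of 16 bases, within the 5 to 6 of 1000 random sets of other barcodes of the library. Yet only 3 barcodes held this chain beside another heavy chain (counting interval 0.619 to 8.77). Mixing of cells predicts 26.4 (20.9 to 32.8) if all other barcodes with 2 or more heavy chains hold mixed cells. If only those that also hold 2 or more light chains do, it predicts 17.5. RNA of a single source in barcodes that hold no other B cell could give such a deficit. Whether it would also give the low light to heavy ratio was not tested, so the ratio does not tell it from a true expansion. A low ratio (0.866, over members with any light chain) was also found in the largest Cre+ lineage. Part of that lineage may be stray RNA too, so its ratio does not weigh for or against this explanation. A single source was predicted to keep the summed heavy-chain UMIs of the 417-cell lineage within the range of single cells. Their sum of 8523 exceeds the 7068 of the cell with the most, so this part of the prediction was not met. No cell of the lineage had more than 57. Stray RNA from more than 1 source was not tested. Stray RNA and a true expansion of IgA cells cannot be told apart with the receptor contigs alone, since the other transcripts of these barcodes were not used here.

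In the Cre+ lineage of 64 cells, part of the members may be other B cells that picked up its RNA. Of the 62 cells with its main CDR3, 48 had its light chain, and 0 of these were unswitched (exact upper bound 7.40%). Of the 12 without that light chain and with a constant gene called, 50% were unswitched (21.1 to 78.9). The constant gene was called on the contig that carries the CDR3, so picked-up IgA RNA alone would be called IgA. The unswitched calls therefore cannot tell such RNA from unswitched members of the lineage. The chain also stood beside another heavy chain in 15 barcodes (8.40 to 24.7), where mixing of cells predicts 5.15 (4.30 to 6.12). Of these 15, 2 held 2 or more light chains, where mixing counted from such barcodes predicts 3.05. No biological explanation of these members was tested.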

How the results depend on the processing

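The tests without the largest lineages were chosen after the data were seen, as were all alternatives for the correlation of IGHV usage. Values are Cre+ minus Cre-, in percentage points unless stated. There were 130 values of 27 results under alternatives planned beforehand. Of these, 109 stayed within the interval of the main difference, 15 moved beyond it and 6 changed sign. Of 60 values of 29 results under alternatives added later, 29 stayed, 15 moved and 16 changed sign. A change of sign was counted only where the main intervals did not overlap, and elsewhere it was counted as stayed or moved. Shared heavy chains and the correlation of IGHV usage had no interval. For these, stayed meant an equal value or a ratio of at most 1.5. No planned choice of barcodes (all with a heavy chain, exactly 1 heavy and 1 light chain, or 3 or more UMIs) moved any of these results beyond its interval. With each lineage and isotype class counted once, the difference was -1.0 for IgA, -0.0470 for IGHV4-1, 1.06 for IGHJ3, -2.40 for J mismatch in switched cells (16.1 in the main setting), -1.09 for IgM, -0.0211 for IgG1 and -0.116 for IGHV5-17. Without the largest lineage of each library it was -0.801 for IgA, 0.864 for cells in lineages of 2 or more, 0.0540 for IGHV4-1, 0.999 for IGHJ3, -2.73 for J mismatch, -1.49 for IgM, -0.301 for IGHV5-17, -0.0474 for IGKV4-72 and 8.64 for IgA cells in lineages of 2 or more, and r of IGHV usage was 0.940. Without the 2 largest lineages of each library these were -0.732, 0.242, 0.0598, 1.16, 0.573, -0.987, -0.285, -0.0375 and 8.34, IgG1 was at -0.0272 and r was 0.944. By construction these settings take out the cells of the largest lineages. IGHV4-1 was at 0.0298 in unswitched and -61.5 in switched cells. The difference in CDRH3 length was 0.291 amino acids by the mean, but the means were 14.01 in Cre+ and 14.12 in Cre- cells without the largest lineages. J mismatch in switched cells was at 32.6 with 12 nucleotides, and at 0.451 (-7.41 to 8.39) when the largest lineages were also left out. The share of lineages with unswitched and switched cells differed by 3.06 in the main setting. It differed by 20 with the authors' clonotypes (4 of 20 against 0 of 15 lineages, -6.05 to 43.7) and by 17.0 with a shared light V gene (0.517 to 31.9). At 80% identity the difference was -0.0807, at 90% it was 5.76 and with identical CDR3s 4.27. The cause of these changes was not tested. No paired analysis was possible because each genotype had 1 pooled library. Depth limits the rare classes: a count of 0 cells allows a share of up to 0.0916% of Cre+ and 0.102% of Cre- cells with a constant gene.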

Other observations

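The heaviest transcript loads came from few cells. The 33 Cre+ cells with the most heavy-chain UMIs, 1% of cells, held 53.2% of the heavy-chain UMIs of cells with exactly 1 heavy chain. The 29 such Cre- cells held 55.4%, so that UMI totals say little about cell numbers here. IgA cells outside the largest lineages had a median of 18.5 heavy-chain UMIs in the Cre+ and 15 in the Cre- library, against 8 and 9 in unswitched cells. The highest single cells reached 4753 and 7068 heavy-chain UMIs.

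In the Cre+ library, 3 of the 7 lineages of 4 or more cells used IGHV1-12, a choice of gene made after the values were seen. They held 8, 6 and 4 cells with unrelated CDR3s (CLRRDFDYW, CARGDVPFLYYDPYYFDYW and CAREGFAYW), and the latter 2 held both IgA and IgG1 cells. In the Cre- library, 0 of the 4 lineages of 4 or more cells used IGHV1-12, and its largest IGHV1-12 lineage had 3 cells. Of all lineages of 2 or more cells, 5 in the Cre+ and 1 in the Cre- library used IGHV1-12.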
